A study of Mus musculus with 14 samples.

How the data were processed

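Bulk RNA sequencing was carried out on CD4+ T cells sorted from a mouse model of chronic graft-versus-host disease (cGVHD). Per the labels, BALB/c recipients were given T-cell-depleted bone marrow from C57BL/6 (B6) donors, either with donor splenocytes, which gave cGVHD, or without them, which gave GVHD-free animals. Spleen, liver and lung were taken 30 days after transplantation, and donor-derived CD4+ T cells were sorted by surface PSGL1 (P-selectin glycoprotein ligand 1, encoded by Selplg) into PSGL1lo and PSGL1hi fractions. The 14 libraries fall into 7 groups of 2: GVHD-free spleen PSGL1lo, and PSGL1lo and PSGL1hi from the spleen, liver and lung of cGVHD animals. RNA was extracted with the Qiagen RNeasy kit and libraries were made with the Kapa mRNA HyperPrep kit, per the labels' protocols. Nothing in the labels says that the replicates of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

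The deposited values are whole-number read counts per gene, not normalised, which the authors made with TopHat2 2.0.8 and HTSeq on the mm9 mouse assembly, per the submitters' processing notes. The gene annotation, the strand setting of the counting, the read length and any read filters are not given in the sources used here. Because the strand setting is unknown, counts of overlapping or antisense genes are uncertain. Counts of genes with near-identical copies are uncertain as well, since reads can match several copies and how these were counted is not given in the sources used here. Among the genes named in the text the latter holds for the histone genes, Hspa1a and Hspa1b, the H2-Q genes, the Klr genes, Serpina3f and Lilr4b. The reference annotation at hand is of another build than mm9 and was used only for names and for which genes neighbour each other, so no coordinates are printed. Of the 25017 gene entries, 26 carry date-like names of the kind spreadsheet software makes from septin and March-type symbols. They hold 0.286% to 0.389% of each library's counts; they were kept under the names in the file, and 20 of them were tested.

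The libraries hold 13222005 to 33532595 counts. A count of 3, the upper limit that a count of 0 allows, equals 0.0895 to 0.227 CPM (counts scaled to a common library total) per library; such floors cover counting error only. Where a group lies at or near the floor, the comparisons give levels without a fold. Fitted differences between tissues that involve such a group depend on the model's prior count and measure no size. The spleen libraries carry library numbers 11255 to 11260 and the liver and lung libraries 24944 to 24951 in the labels, so tissue and library series cannot be told apart for any contrast of spleen with liver or lung, whereas the contrasts of PSGL1lo with PSGL1hi and of cGVHD with GVHD-free cells each lie within one series. The liver and lung library names also carry a number that goes with PSGL1hi in liver and with PSGL1lo in lung, with no meaning given in the labels; the fractions were taken from the sample labels. Counts of the 2 replicates of every group differed by more than sampling noise (chi-square per degree of freedom of 3.04 to 19.6), so no library appeared to be a copy of another.

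Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings, which left 13780, library sizes were scaled by TMM, and a quasi-likelihood negative binomial model with one mean per group was fitted to all 14 libraries (7 residual degrees of freedom, common biological coefficient of variation 7.35%). Contrasts were tested 2-sided by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes tested, and an adjusted p under 0.05 was called a change. Every adjusted p of a single gene below is from this test. Standard errors (SE) of log2 changes were computed from the F statistic, and levels are TMM-scaled CPM as mean ± SD of 2 libraries. The contrasts were cGVHD against GVHD-free spleen PSGL1lo, PSGL1lo against PSGL1hi in each of the 3 tissues, the 3 differences of the PSGL1lo effect between tissues, lung against liver in each fraction, and liver and lung against spleen in PSGL1lo cells. Genes called in the same direction in all 3 tissues were counted as changed alike.

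Gene lists were fixed for 25 groups. For T cell states they cover T follicular helper cells and B cell help, tissue residency, circulation and tissue egress, naive and memory T cells, Th1 and cytotoxic genes, Th2, Th17, regulatory T cells, inhibitory receptors and exhaustion, proliferation, interferon-stimulated genes, chemokine receptors and integrins, glycolysis and hypoxia, selectin ligand synthesis, and cytokines with the TNF family. A separate list of immediate early and stress genes was set as a sign of sample quality. For other cells in the tissues or the gate they cover B and plasma cells, CD8 T cells, natural killer (NK) cells, NKT and gamma delta T cells, myeloid cells, hepatocytes, lung epithelium, endothelium with stroma, and erythroid cells. Lists were tested against the other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. The test was repeated with the correlation estimated from the data and with fry, which asks whether a list's genes move on balance one way and not whether they differ from other genes. The CD8 T cell and erythroid lists had only 2 tested members each, so their genes are given singly. Some lists share members, so their calls are not independent. The follicular helper list shares members with the inhibitory receptor list, Pdcd1, Tox and Cd200 among them. The tissue residency list shares members with the immediate early and stress list, Nr4a1 among them.

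Genes named in the text were set by a rule. It takes 18 fixed genes, 17 of them named here (Selplg, Bcl6, Cxcr5, Pdcd1, Icos, Il21, Cd40lg, Prdm1, Cxcr6, Cd69, Itgae, Ccr7, S1pr1, Klf2, Foxp3, Ifng and Gzmb) whatever their p. It then takes the 5 largest increases and 5 largest decreases (3 and 3 for differences between tissues) with a mean of at least 20 CPM and no overlap between the groups' libraries, leaving out Gm-numbered, Rik and immunoglobulin or T cell receptor segment entries, and up to 4 members of each list with the largest change at a mean of at least 5 CPM. Some genes that the rule takes are not reported here. Genes from outside the rule are said to be such where they appear. The grouping, the contrasts, the main test, the gene lists, the rule for named genes and all alternatives but one were chosen before the data were examined.

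The alternatives were DESeq2's size factors, no filter on low counts, a filter of at least 5 CPM in at least 2 libraries, DESeq2 1.42.0's Wald test, limma voom with quality weights, fits to only the groups of a contrast or only its library series, the replicate number as a block, a test against a 1.5-fold change (glmTreat), and leaving out each library in turn, which assumes that the lone library left in a group varies like the other groups. Leaving out 237 RNAs that lack a poly(A) tail was added after seeing the data. No alternative scaling moved the share of higher against lower calls by more than 10 percentage points. The model was tested on simulated counts with a single mean per gene over all libraries and the library sizes and spread of the real samples. In each simulated contrast 200 genes of at least 5 CPM were changed, as many up as down. The shares below hold for that setting, which has far fewer changed genes than the main test called in the real contrasts. Of the genes changed 1.5-fold, edgeR recovered 76.1% in the simulated disease contrast (13268 genes run), 80.6% in spleen (13270), 85.1% in liver (13264) and 85.1% in lung (13267). At a 2-fold change it recovered 95.5%, 98.5%, 98.5% and 98.5%, and at a 4-fold change 100% in each. Unchanged genes made up 7.65%, 6.06%, 5.5% and 5.97% of the calls in the same order.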

Results

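Gene expression was measured by bulk RNA sequencing in donor-derived CD4+ T cells that had been sorted into PSGL1lo and PSGL1hi fractions 30 days after allogeneic transplantation in mice. Of the 14 libraries, 2 came from spleen PSGL1lo cells of GVHD-free recipients. The other 12 came from cGVHD recipients, 2 each for the PSGL1lo and PSGL1hi fractions of spleen, liver and lung. Total counts per library were 15486585 and 13222005 in GVHD-free spleen PSGL1lo, 13283091 and 14905806 in cGVHD spleen PSGL1lo and 21346229 and 23000993 in cGVHD spleen PSGL1hi cells. Liver libraries held 33532595 and 23054577 counts in PSGL1lo and 22380631 and 28033026 in PSGL1hi cells. Lung libraries held 23568133 and 22417120 counts in PSGL1lo and 25578595 and 28413717 in PSGL1hi cells. Levels are given as CPM (mean ± SD, n = 2 libraries per group) and changes as log2 ratio ± SE. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13780 genes. Of the replicate pairs, liver PSGL1lo varied most, with a biological coefficient of variation of 12.3% against 3.8% in the closest pair.

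**Figure D1:**
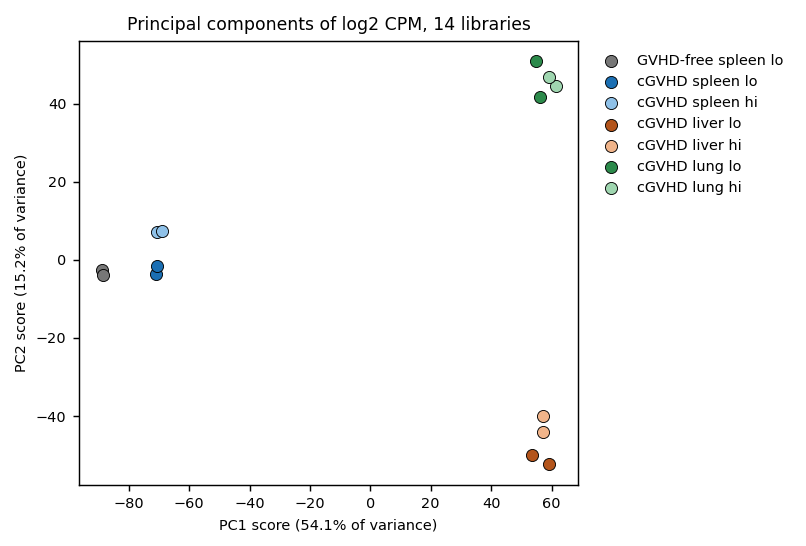
Principal components of log2 CPM of the 14 libraries, PC1 (54.1% of variance) on the horizontal and PC2 (15.2%) on the vertical axis, each point a library coloured by group. Spleen libraries sit at PC1 scores of -88.95 to -68.95 and liver and lung libraries at 53.62 to 61.31, while PC2 separates liver from lung.

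In the spleen, PSGL1lo cells of cGVHD recipients held fewer transcripts of follicular helper T cells than those of GVHD-free recipients and more Th1, cytotoxic and tissue residency ones (list adjusted p = 4.8e-06, 5.11e-14 and 2.49e-05). Only the cGVHD recipients were given donor splenocytes, so disease and the source of the donor T cells cannot be told apart in this comparison. Ccr7, a chemokine receptor of cells that home to lymph nodes, averaged 141 ± 4.3 CPM in GVHD-free and 26.9 ± 0.77 CPM in cGVHD cells (log2 change -2.39 ± 0.12, adjusted p = 9.5e-13). Foxp3, the lineage factor of regulatory T cells, fell from 56.3 ± 2.3 to 3.92 ± 0.46 CPM (adjusted p = 3.1e-14). Cxcr6, a chemokine receptor of tissue-homing T cells, rose from 86.9 ± 2 to 529 ± 14 CPM (adjusted p = 1.7e-15). The follicular regulators went down, Cxcr5 from 245 ± 3.5 to 58.7 ± 2.7 CPM and Bcl6 from 85.6 ± 6.8 to 29.1 ± 1.1 CPM (adjusted p = 2.1e-13 and 1.2e-09). The helper cytokine Il21 went up from 170 ± 2.1 to 246 ± 1.2 CPM (adjusted p = 6.2e-05).

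Of 13780 genes, 3791 changed between cGVHD and GVHD-free cells, 2024 higher and 1767 lower in cGVHD, and 1181 passed the test against a 1.5-fold change. Selplg itself was higher in cGVHD PSGL1lo cells, 259 ± 30 against 153 ± 10 CPM (adjusted p = 1.3e-06). Prdm1, which encodes the Bcl6 antagonist Blimp-1, rose by 1.55 ± 0.10 on the log2 scale and Ifng by 0.81 ± 0.08. Cd69, an early activation and retention marker, rose by 0.71 ± 0.10, and the costimulatory genes Icos and Cd40lg by 0.51 ± 0.07 and 0.51 ± 0.09. Besides Ccr7, the genes of circulating cells S1pr1 (-0.60 ± 0.09) and Klf2 (-0.63 ± 0.14) were lower in cGVHD. Itgae, which encodes the integrin chain CD103, was lower by -2.59 ± 0.10. Gzmb was 91.5 ± 2.4 CPM in GVHD-free and 99.1 ± 2.4 CPM in cGVHD cells (adjusted p = 0.62). Pdcd1 was lower in cGVHD by a small margin, 383 ± 20 against 463 ± 16 CPM (log2 change -0.27 ± 0.07, adjusted p = 0.0071). That call was lost without cGVHD spleen PSGL1lo replicate 2 (log2 change -0.22) and without GVHD-free replicate 2 (-0.24).

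The leading increases in cGVHD included Padi2, a peptidylarginine deiminase, from 6.99 ± 0.97 to 99 ± 10 CPM, and the aspartyl protease Bace2, from 4.22 ± 0.11 to 57.2 ± 1.4 CPM. Baiap3 went from 13.2 ± 0.94 to 160 ± 21 CPM and the inhibitory receptor gene Lilr4b from 13.4 ± 1.9 to 136 ± 3.3 CPM. The serpin Serpina3f went from 17.4 ± 0.017 to 160 ± 0.89 CPM. Among the leading decreases, Pou2af1, a coactivator in B cells and follicular helper T cells, fell from 62.3 ± 1.4 to 3.89 ± 1.2 CPM (adjusted p = 1.4e-12). H2-Q2, a class I gene of the histocompatibility block, averaged 85 ± 1.2 CPM in GVHD-free and 3.34 ± 0.014 CPM in cGVHD cells. Rprl3, a small RNA gene, averaged 354 ± 6.8 and 0.951 ± 0.24 CPM. Zan averaged 55.9 ± 2.7 CPM in GVHD-free and 0.173 ± 0.033 CPM in cGVHD cells, where the level lay at that of 3 counts or below.

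The T follicular helper and B cell help list moved down in cGVHD, with 5 of its 26 tested members higher, 16 lower and 5 not past the test (6 and 17 when adjusted over the list alone, list adjusted p = 4.8e-06). The cytokine receptor genes Il6ra (-2.56 ± 0.15) and Il6st (-2.45 ± 0.10) were among the lower members, while Icos, Il21 and Cd40lg were among the higher. In contrast, the Th1 and cytotoxic list moved up, with 17 of 22 higher and 1 lower, the same counts adjusted over the list alone (list adjusted p = 5.11e-14). They included the cathepsin gene Ctsw (2.06 ± 0.09), the transcriptional regulator Hopx (1.94 ± 0.09) and the interleukin-18 receptor subunit Il18rap (1.84 ± 0.11). In the tissue residency list 14 of 23 members rose and 4 fell, again the same counts adjusted over the list alone (list adjusted p = 2.49e-05). The collagen-binding integrin Itga1 rose by 3.44 ± 0.23, and Itgae was among those that fell. Of 10 Th2 members 7 rose and 0 fell, also when adjusted over the list alone (list adjusted p = 7.31e-06). Il13 rose by 2.46 ± 0.26, the interleukin-33 receptor Il1rl1 by 1.69 ± 0.12 and Ccr8 by 1.52 ± 0.12. Glycolysis and hypoxia genes were higher in 12 of 19 and lower in 0 members, over all genes and adjusted over the list alone (list adjusted p = 7.76e-06). Among them the glycolytic enzyme Tpi1 rose by 0.84 ± 0.09. Inhibitory receptors and exhaustion genes moved down, 1 member higher and 8 of 16 lower (1 and 10 adjusted over the list alone, list adjusted p = 3.63e-05). Nrn1 was lower by -3.14 ± 0.17 and the ectonucleotidase Nt5e by -2.13 ± 0.10. The inhibitory receptor list shares members, Pdcd1 among them, with the follicular helper list. These 6 list calls held with an estimated correlation.

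Further lists were called at the preset correlation and not with an estimated one. Naive and memory T cell genes were higher in 3 of 18 and lower in 12 members (3 and 13 adjusted over the list alone). The list's adjusted p = 7.31e-06, and adjusted p = 0.0514 with an estimated correlation. In the regulatory T cell list 3 of 16 were higher and 9 lower, the same adjusted over the list alone (list adjusted p = 0.000126, adjusted p = 0.0514 with an estimated correlation). Lrrc32 changed by -4.11 ± 0.22 and Ikzf2 by -2.11 ± 0.09. Chemokine receptors and integrins rose in 14 of 23 and fell in 5 members (16 and 5 adjusted over the list alone, list adjusted p = 0.000166, adjusted p = 0.0596 with an estimated correlation). The integrin gene Itga2 rose by 2.52 ± 0.16. Of 28 cytokine and TNF family genes 13 were higher and 4 lower (14 and 5 adjusted over the list alone, list adjusted p = 0.00291, adjusted p = 0.0702 with an estimated correlation). Csf2, the gene of the growth factor GM-CSF, rose by 1.72 ± 0.21. Proliferation genes were higher in 8 of 26 and lower in 0 members (10 and 0 adjusted over the list alone, list adjusted p = 0.00381, adjusted p = 0.645 with an estimated correlation). Mki67 rose by 0.56 ± 0.07.

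Markers of other cell types moved in the same comparison. In the B and plasma cell list 8 of 10 tested members were lower in cGVHD and 0 higher, the same adjusted over the list alone (list adjusted p = 9.13e-05, adjusted p = 0.0237 with an estimated correlation). Cd22 changed by -1.74 ± 0.18 and Jchain by -1.30 ± 0.27. All 3 tested members of the NKT and gamma delta T cell list were lower, also when adjusted over the list alone (list adjusted p = 0.00291, adjusted p = 0.0485 with an estimated correlation). The myeloid list was not called (adjusted p = 0.448, 4 higher and 5 lower of 18), but its complement gene C1qa was higher in cGVHD, at 30 ± 0.91 against 7.01 ± 0.69 CPM. The erythroid gene Alas2 rose by 0.88 ± 0.22 (adjusted p = 0.0043), a call lost without cGVHD spleen PSGL1lo replicate 1 (0.81) or GVHD-free replicate 2 (0.80). The CD8 T cell gene Cd8a averaged 3.53 ± 0.076 CPM in GVHD-free and 4.73 ± 0.58 CPM in cGVHD cells.

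The T cell lists for circulation and egress (adjusted p = 0.402) and Th17 (0.613) were not called in the disease comparison. Nor were interferon-stimulated genes (0.879), immediate early and stress genes (0.208) and selectin ligand synthesis (0.0867, or 0.0483 with no filter on low counts). Of the other cell types, NK cells (0.225), hepatocytes (0.448), lung epithelium (0.726) and endothelium with stroma (0.638) were not called. The Th17 list had a median of -0.82 and a mean of 0.06, and the NK list -0.22 and 0.21. For interferon-stimulated genes the median was 0.01 and the mean -0.13, and for lung epithelium the median was 0 and the mean 0.26 under a test pointing down.

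The sorted fractions were compared within each cGVHD tissue to find how PSGL1lo cells differ from PSGL1hi cells of the same organ. Selplg, the gene of the sorted protein, was lower in the PSGL1lo fraction of each tissue. It stood at 259 ± 30 against 503 ± 17 CPM in spleen, 576 ± 51 against 923 ± 20 CPM in liver and 420 ± 52 against 960 ± 49 CPM in lung (adjusted p = 5e-08, 7.9e-06 and 1.1e-09).

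**Figure D2:**
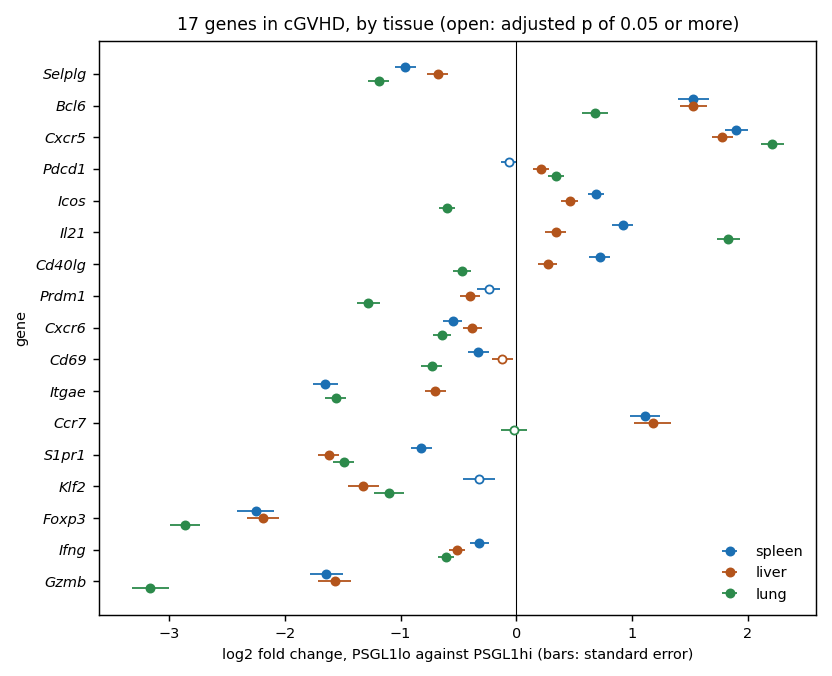
Log2 ratio of PSGL1lo to PSGL1hi (horizontal axis, ± SE) for 17 fixed genes in cGVHD spleen, liver and lung, with open symbols where the adjusted p was 0.05 or more. Cxcr5 lies to the right in each tissue (1.90, 1.78 and 2.21) and Foxp3 to the left (-2.25, -2.19 and -2.86), while Icos lies at 0.69 and 0.46 in spleen and liver and at -0.60 in lung.

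In cGVHD spleen, PSGL1lo cells held more of the transcripts of follicular helper T cells and fewer of the Th1 and cytotoxic ones (list adjusted p = 6.86e-13 and 9.25e-10). Cxcr5, the follicle-homing receptor, averaged 58.7 ± 2.7 CPM in PSGL1lo and 15.8 ± 0.026 CPM in PSGL1hi cells, and Bcl6 29.1 ± 1.1 and 10.1 ± 1.4 CPM (adjusted p = 1.7e-11 and 1.8e-08). Genes of B cell help were higher too, with Il21 at 246 ± 1.2 against 130 ± 3.7 CPM, Icos at 523 ± 11 against 325 ± 6.8 CPM and Cd40lg at 94.5 ± 7.4 against 57.3 ± 2.1 CPM. Granzyme B (Gzmb) went the other way, 99.1 ± 2.4 CPM in PSGL1lo and 309 ± 5.4 CPM in PSGL1hi cells (adjusted p = 1.6e-08). Foxp3 averaged 3.92 ± 0.46 and 18.6 ± 2.8 CPM (adjusted p = 9e-10).

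The comparison gave 4483 changed genes, 2177 higher and 2306 lower in PSGL1lo cells, of which 776 passed the test against a 1.5-fold change. Among the egress genes, the sphingosine-1-phosphate receptor S1pr1 was lower by a log2 change of -0.82 ± 0.09. Ccr7 was higher by 1.11 ± 0.13 (adjusted p = 7.5e-07). Itgae (-1.65 ± 0.11), Cxcr6 (-0.55 ± 0.08) and Ifng (-0.32 ± 0.08) were lower in PSGL1lo cells. Pdcd1, Prdm1 and Klf2 did not pass the test, with log2 changes of -0.06 ± 0.07, -0.24 ± 0.10 and -0.32 ± 0.14 (adjusted p = 0.57, 0.057 and 0.079). With no filter on low counts, or only the spleen groups in the model, Prdm1 (-0.25 and -0.24) and Klf2 (-0.32 in both) were called, and with voom Prdm1 (-0.24). Cd69 was lower by -0.33 ± 0.09 (adjusted p = 0.0094), a call lost without spleen PSGL1hi replicate 2 (-0.24) and without spleen PSGL1lo replicate 1 (-0.30).

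The leading increases in spleen PSGL1lo cells included Lrig1, a negative regulator of growth factor receptors, at 39.7 ± 0.42 against 4.16 ± 0.53 CPM. Tcf7, which encodes the stem- and memory-associated factor TCF-1, stood at 294 ± 16 against 56.8 ± 0.17 CPM. Ttn, the gene of the muscle protein titin, stood at 780 ± 4.3 against 149 ± 4.7 CPM, Nsg2 at 75.3 ± 7.9 against 14.5 ± 0.11 CPM and Igf1r at 37.3 ± 2 against 7.53 ± 0.14 CPM. The leading decreases included Ifitm1 (4.41 ± 0.51 against 50.6 ± 4.7 CPM), Ggt1 (6.16 ± 1.5 against 45.6 ± 0.11 CPM) and the inhibitory NK receptor gene Klrc1 (8.42 ± 0.85 against 56.6 ± 11 CPM). Jchain, the joining chain of secreted antibodies, stood at 4.22 ± 1.4 against 44.9 ± 5.9 CPM, and Cd8a at 4.73 ± 0.58 against 46.7 ± 0.78 CPM.

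In the T follicular helper and B cell help list 19 of 26 members were higher and 1 lower in spleen PSGL1lo cells, the same counts adjusted over the list alone (list adjusted p = 6.86e-13, and adjusted p = 0.0137 with an estimated correlation). The interleukin-6 receptor gene Il6ra was higher by 1.92 ± 0.18 and Gpm6b by 1.68 ± 0.13. Th1 and cytotoxic genes were lower in 17 of 22 and higher in 2 members, also over the list alone (list adjusted p = 9.25e-10, adjusted p = 0.029 with an estimated correlation). Perforin (Prf1) changed by -1.97 ± 0.09 and Gzma by -2.10 ± 0.23. Beside them, the CD8 T cell markers Cd8a and Cd8b1 changed by -3.31 ± 0.13 and -2.07 ± 0.14. The NK cell list was lower in 4 of 6 members, over all genes and adjusted over the list alone (list adjusted p = 0.00635, adjusted p = 0.226 with an estimated correlation). All 26 proliferation genes were lower in PSGL1lo cells, over all genes and adjusted over the list alone (list adjusted p = 2.82e-22, adjusted p = 0.141 with an estimated correlation). Examples were the cyclin genes Ccnb1 (-1.79 ± 0.19) and Ccna2 (-1.54 ± 0.12) and the kinase Cdk1 (-1.60 ± 0.13). The circulation and egress list had 12 of 17 members lower and 1 higher (13 and 1 adjusted over the list alone, list adjusted p = 1.55e-07, adjusted p = 0.0761 with an estimated correlation). Klrg1, a receptor of short-lived effector cells, changed by -2.09 ± 0.13. Of 10 Th2 genes 7 were lower and 1 higher, over all genes and adjusted over the list alone (list adjusted p = 0.00583, adjusted p = 0.141 with an estimated correlation). Il13 changed by -2.17 ± 0.19 and Il1rl1 by -2.04 ± 0.11.

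The interferon-stimulated list had 11 of 22 members higher and 2 lower in spleen PSGL1lo cells, the same adjusted over the list alone (list adjusted p = 0.00516, adjusted p = 0.42 with an estimated correlation). Ifit1 was higher by 0.79 ± 0.12. Glycolysis and hypoxia genes were lower in 9 of 19 and higher in 2 members (11 and 2 adjusted over the list alone, list adjusted p = 0.0237, adjusted p = 0.378 with an estimated correlation). The glucose transporter Slc2a3 changed by -0.80 ± 0.07. That list call was also lost without spleen PSGL1hi replicate 1 (adjusted p = 0.0559) and without spleen PSGL1lo replicate 2 (0.0704). The myeloid list was lower in 9 of 18 and higher in 0 members (10 and 0 adjusted over the list alone, list adjusted p = 0.00157, adjusted p = 0.42 with an estimated correlation). C1qa averaged 30 ± 0.91 CPM in PSGL1lo and 70.6 ± 3.1 CPM in PSGL1hi cells. The erythroid gene Alas2 averaged 17.1 ± 1.2 CPM in PSGL1lo and 21.4 ± 0.69 CPM in PSGL1hi cells.

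Among the T cell lists, tissue residency (adjusted p = 0.482), naive and memory T cells (0.12), Th17 (0.482), regulatory T cells (0.202) and inhibitory receptors (0.101) were not called in spleen. The same held for immediate early and stress genes (0.059), chemokine receptors and integrins (0.059), selectin ligand synthesis (0.289) and cytokines with the TNF family (0.775). The chemokine receptor list was called with no filter on low counts (0.0332) and without spleen PSGL1lo replicate 1 (0.0464), and the immediate early list without spleen PSGL1hi replicate 1 (0.0255). B and plasma cells (0.343), NKT and gamma delta T cells (0.289), hepatocytes (0.81), lung epithelium (0.861) and endothelium with stroma (0.927) were not called either. For the cytokine list the median was 0.05 and the mean -0.12 under a test pointing up, and for the hepatocyte list the mean was 0.08 under a test pointing down.

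**Figure D3:**
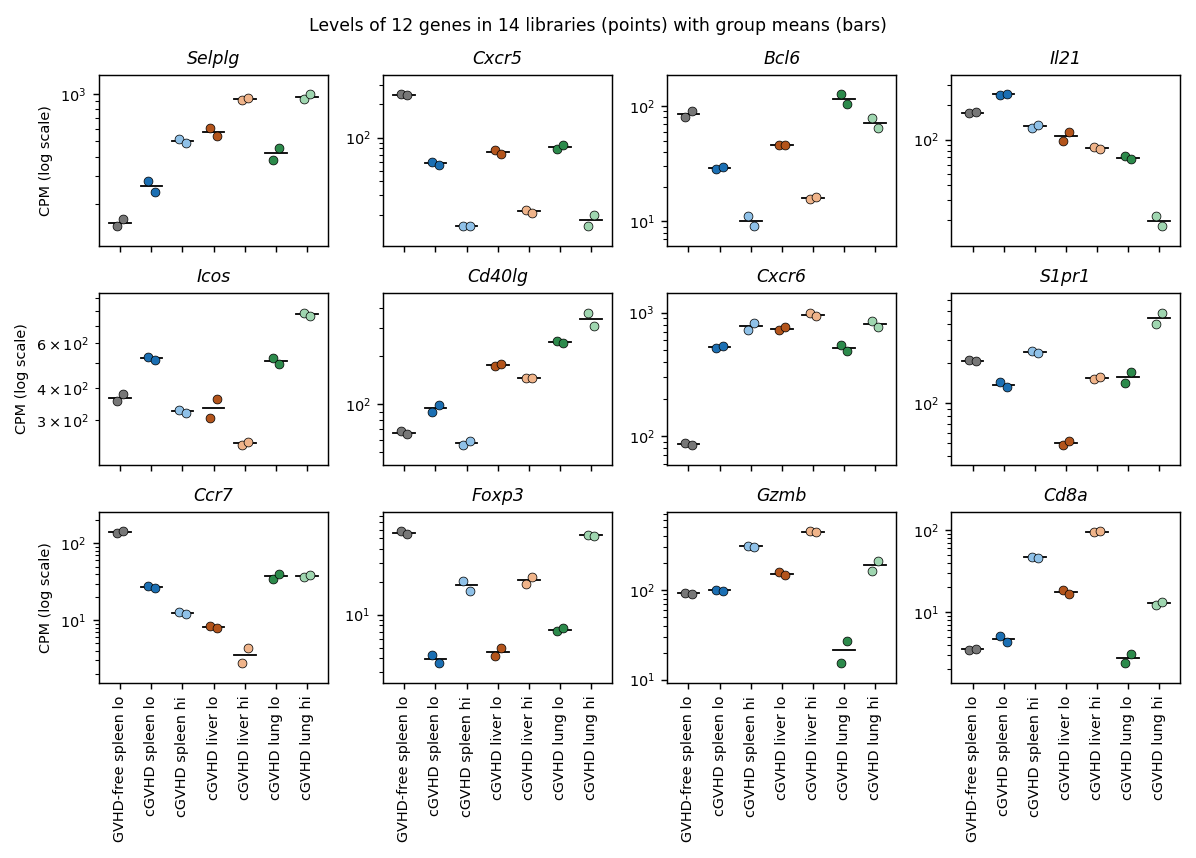
Levels of 12 genes (log vertical axis, CPM) in each of the 14 libraries, one point per library and a bar at the mean of each of the 7 groups. Cxcr5 and Bcl6 stand higher in PSGL1lo than PSGL1hi cells of each cGVHD tissue, and S1pr1 and Foxp3 lower, with S1pr1 at 50.5 CPM in liver PSGL1lo and 441 CPM in lung PSGL1hi cells.

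In cGVHD liver, the follicular genes were again higher in PSGL1lo cells, Cxcr5 at 74 ± 4.8 against 21.5 ± 0.87 CPM and Bcl6 at 45.8 ± 0.42 against 15.8 ± 0.3 CPM (adjusted p = 1.7e-11 and 5.1e-09). The egress receptor S1pr1 and its transcription factor Klf2 were lower, at 50.5 ± 2.6 against 155 ± 3.4 CPM and 63.7 ± 6.5 against 160 ± 2.7 CPM (adjusted p = 6e-11 and 2.2e-07). Gzmb stood at 151 ± 8.3 CPM in PSGL1lo and 450 ± 3.2 CPM in PSGL1hi cells, and Foxp3 at 4.59 ± 0.54 and 20.7 ± 2.2 CPM. Cxcl10, a ligand of the Th1 receptor CXCR3, was higher in PSGL1lo cells, at 46.6 ± 2 against 8.08 ± 0.57 CPM (adjusted p = 1.1e-11).

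In this tissue 2866 genes changed, 1171 higher and 1695 lower in PSGL1lo cells, and 472 passed the test against a 1.5-fold change. The count fell to 1580 without liver PSGL1hi replicate 1 and to 1696 without liver PSGL1hi replicate 2. Icos (0.46 ± 0.07) and Ccr7 (1.18 ± 0.16) were higher in PSGL1lo cells. Itgae (-0.70 ± 0.09), Ifng (-0.51 ± 0.07), Prdm1 (-0.40 ± 0.09) and Cxcr6 (-0.38 ± 0.08) were lower. Cd69 at -0.12 ± 0.09 did not pass the test (adjusted p = 0.4), but was called without liver PSGL1lo replicate 2 (-0.29). Small increases of Il21 (0.34 ± 0.09, adjusted p = 0.0074), Cd40lg (0.27 ± 0.08, adjusted p = 0.025) and Pdcd1 (0.21 ± 0.07, adjusted p = 0.039) were called with all libraries in the fit. The Il21 call was lost without PSGL1hi replicate 2 (0.31) or PSGL1lo replicate 2 (0.20). That of Cd40lg was lost without PSGL1hi replicate 1 (0.26), PSGL1hi replicate 2 (0.26) or PSGL1lo replicate 2 (0.24). For Pdcd1 it was lost without PSGL1hi replicate 1 (0.18), PSGL1hi replicate 2 (0.25) or PSGL1lo replicate 1 (0.13), and with only the liver groups in the fit (0.24).

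The leading increases in liver PSGL1lo cells were Lrig1 (2.75 ± 0.11), Cxcl10 (2.52 ± 0.13), Bace2 (2.21 ± 0.11), Nsg2 (1.99 ± 0.11) and Il1r2, the decoy receptor for interleukin-1 (1.91 ± 0.12). Of the leading decreases, Ifitm1 stood at 10.3 ± 2.3 against 175 ± 7.5 CPM and Rap1gap2 at 10.6 ± 3.2 against 60 ± 4.5 CPM. Cd8a stood at 17.7 ± 1.3 against 95.8 ± 1.4 CPM, Klrc1 at 7.98 ± 1.9 against 39.9 ± 2.4 CPM and Gzma at 62.3 ± 8.2 against 295 ± 3.8 CPM.

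In the follicular helper and B cell help list 21 of 26 members were higher and 0 lower in liver PSGL1lo cells (22 and 0 adjusted over the list alone, list adjusted p = 8.23e-19, and adjusted p = 0.00396 with an estimated correlation). The signalling lymphocyte receptor Slamf6 was higher by 1.31 ± 0.07. Th1 and cytotoxic genes were lower in 15 of 22 and higher in 1 (18 and 1 adjusted over the list alone, list adjusted p = 1.87e-11, adjusted p = 0.0181 with an estimated correlation). Prf1 changed by -1.39 ± 0.08, and alongside these genes Cd8b1 changed by -1.91 ± 0.12. The NK list was lower in 3 of 6 members, also when adjusted over the list alone (list adjusted p = 0.00293, adjusted p = 0.169 with an estimated correlation). Klre1 averaged 5.02 ± 0.1 against 17.7 ± 2.4 CPM, and the NK list call was lost without liver PSGL1lo replicate 2. Circulation and egress genes were lower in 13 of 17 and higher in 1 (13 and 2 adjusted over the list alone, list adjusted p = 3.3e-10, adjusted p = 0.0338 with an estimated correlation). Rasgrp2 changed by -1.78 ± 0.11. Of 11 Th17 genes 9 were lower and 0 higher, also when adjusted over the list alone (list adjusted p = 6.46e-08, adjusted p = 0.0689 with an estimated correlation). Il17re changed by -2.45 ± 0.28 and the interleukin-1 receptor gene Il1r1 by -1.74 ± 0.14. Proliferation genes were lower in 24 of 26 (25 adjusted over the list alone, list adjusted p = 4.53e-16, adjusted p = 0.169 with an estimated correlation), Ccna2 by -0.98 ± 0.12. Interferon-stimulated genes were higher in 10 of 22 (11 adjusted over the list alone, list adjusted p = 0.000113, adjusted p = 0.343 with an estimated correlation), Oasl2 by 1.06 ± 0.18.

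Hepatocyte transcripts were higher in liver PSGL1lo than PSGL1hi libraries for 7 of 10 tested members and lower for 0, over all genes and adjusted over the list alone (list adjusted p = 0.000581, adjusted p = 0.0861 with an estimated correlation). Albumin (Alb) averaged 35.3 ± 4.9 CPM in PSGL1lo and 14.7 ± 2.2 CPM in PSGL1hi cells. The myeloid list was not called in liver (adjusted p = 0.705). It was called lower in PSGL1lo cells without liver PSGL1lo replicate 1 (adjusted p = 0.000555) and higher without liver PSGL1lo replicate 2 (0.0366). Tissue residency (0.341), naive and memory T cells (0.727), Th2 (0.341), regulatory T cells (0.691), inhibitory receptors (0.103), immediate early and stress genes (0.346) and chemokine receptors with integrins (0.263) were not called. Neither were glycolysis (0.13) and selectin ligand synthesis (0.0882), although without liver PSGL1lo replicate 1 they were (0.018 and 0.046), and the latter also with no filter on low counts (0.0298). Cytokines (0.341), B and plasma cells (0.634), NKT and gamma delta T cells (0.216), lung epithelium (0.691) and endothelium (0.691) were not called. The immediate early list had a median of 0.08 and a mean of -0.06, and the cytokine list 0.25 and -0.31. The naive and memory list and the B cell list had medians of -0.05 and -0.14 under a test pointing up.

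In cGVHD lung, PSGL1lo cells had 82.6 ± 5.2 CPM of Cxcr5 against 17.8 ± 2.7 CPM in PSGL1hi cells and 69.7 ± 2.4 against 19.7 ± 2.8 CPM of Il21 (adjusted p = 6.8e-13 and 9.3e-12). Bcl6 was higher by a smaller margin, 115 ± 16 against 71.6 ± 10 CPM (adjusted p = 3e-05). The costimulatory genes Icos and Cd40lg were lower, at 512 ± 21 against 775 ± 16 CPM and 245 ± 4.4 against 340 ± 47 CPM (adjusted p = 1.4e-06 and 1e-04). Gzmb averaged 21.2 ± 8.5 CPM in PSGL1lo and 189 ± 34 CPM in PSGL1hi cells, S1pr1 157 ± 20 and 441 ± 58 CPM, and Foxp3 7.29 ± 0.3 and 53.1 ± 0.61 CPM. The leading increase was Sostdc1, which encodes a secreted antagonist of BMP and Wnt signalling, at 62.1 ± 1 CPM in PSGL1lo and 0.781 ± 0.0039 CPM in PSGL1hi cells (adjusted p = 5.8e-17).

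Of the genes tested, 4546 changed in lung, 1774 higher and 2772 lower in PSGL1lo cells, and 1034 passed the test against a 1.5-fold change. Pdcd1 was higher by 0.34 ± 0.07 (adjusted p = 0.00098). Prdm1 (-1.28 ± 0.10), Itgae (-1.56 ± 0.09) and Klf2 (-1.10 ± 0.13) were lower, as were Cd69 (-0.73 ± 0.09), Cxcr6 (-0.64 ± 0.08) and Ifng (-0.61 ± 0.07). Ccr7 was at -0.02 ± 0.11 (adjusted p = 0.91). After Sostdc1 the leading increases were Lad1 at 38.7 ± 12 against 3.13 ± 0.22 CPM and the calcium channel gene Cacna1d at 42.5 ± 9.7 against 4.05 ± 0.097 CPM. Bace2 stood at 66.4 ± 2.5 against 9.12 ± 0.55 CPM and the actin-severing protein gene Scin at 50.6 ± 6.9 against 7.71 ± 0.65 CPM. Among the leading decreases were Gzma (9.93 ± 5.4 against 109 ± 42 CPM), Rap1gap2 (19.1 ± 5 against 117 ± 23 CPM) and Gcnt2 (6.5 ± 1.1 against 35.7 ± 0.71 CPM), besides Gzmb and Foxp3.

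The follicular helper and B cell help list was higher in 19 and lower in 3 of its 26 members in lung PSGL1lo cells, the same adjusted over the list alone (list adjusted p = 3.19e-14, and adjusted p = 0.0101 with an estimated correlation). Gpm6b was higher by 2.58 ± 0.13 and the angiopoietin-like gene Angptl2 by 2.21 ± 0.10. Inhibitory receptors and exhaustion genes were higher in 11 of 16 and lower in 3 (12 and 3 adjusted over the list alone, list adjusted p = 3.06e-05, adjusted p = 0.0244 with an estimated correlation). Nrn1 (2.67 ± 0.17), Cd200 (1.80 ± 0.10) and the exhaustion-associated factor Tox (1.12 ± 0.07) were higher. Cd200 and Tox also belong to the follicular helper list, so the calls of these lists are not independent. Th1 and cytotoxic genes were lower in 20 of 22 and higher in 2, over all genes and adjusted over the list alone (list adjusted p = 7.13e-13, adjusted p = 0.0128 with an estimated correlation). The death ligand Fasl changed by -1.76 ± 0.08. The CD8 T cell markers moved with them, Cd8a at 2.73 ± 0.5 against 12.8 ± 0.74 CPM and Cd8b1 at 9.5 ± 0.3 against 16.7 ± 0.76 CPM. Circulation and egress genes were lower in 13 of 17 and higher in 0, the same adjusted over the list alone (list adjusted p = 1.97e-09, adjusted p = 0.0315 with an estimated correlation). Klrg1 changed by -2.27 ± 0.13.

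Other lists were called lower in lung PSGL1lo cells at the preset correlation and not with an estimated one, each with the same counts adjusted over the list alone. Proliferation genes were lower in 25 of 26 (list adjusted p = 1.05e-22, adjusted p = 0.0982 with an estimated correlation), Cdc6 by -2.36 ± 0.14. Th17 genes were lower in 10 of 11 (list adjusted p = 2.62e-05, adjusted p = 0.102 with an estimated correlation), Il1r1 by -1.45 ± 0.14. Tissue residency genes were lower in 14 of 23 and higher in 4 (list adjusted p = 0.00023, adjusted p = 0.0982 with an estimated correlation). The adhesion gene Cdh1 changed by -1.84 ± 0.10 and the chemokine gene Xcl1 by 1.57 ± 0.14. Immediate early and stress genes were lower in 13 of 20 (list adjusted p = 0.00032, adjusted p = 0.196 with an estimated correlation), Atf3 by -1.47 ± 0.12. Glycolysis and hypoxia genes were lower in 9 of 19 (list adjusted p = 0.00053, adjusted p = 0.106 with an estimated correlation), the hexokinase Hk2 by -1.33 ± 0.11. Of 23 chemokine receptors and integrins 12 were lower and 3 higher (list adjusted p = 0.000527, adjusted p = 0.105 with an estimated correlation), Ccr2 by -2.36 ± 0.10. Of 10 Th2 genes 6 were lower and 1 higher (list adjusted p = 0.00798, adjusted p = 0.105 with an estimated correlation), Il10 by -1.69 ± 0.10.

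Lists not called in lung were naive and memory T cells (adjusted p = 0.179), regulatory T cells (0.796), interferon-stimulated genes (0.597), selectin ligand synthesis (0.149) and cytokines (0.87). Markers of B and plasma cells (0.217), NK cells (0.201, or 0.0399 with no filter on low counts), NKT and gamma delta T cells (0.571), hepatocytes (0.796), lung epithelium (0.908) and endothelium (0.597) were not called either. Nor was the myeloid list (0.189), which was called higher in PSGL1lo cells without lung PSGL1lo replicate 1 (0.0117). The regulatory list had 8 members higher and 6 lower, with a median of 0.17 and a mean of -0.18. The median and mean were 0.01 and -0.29 for the NKT and gamma delta list and 0.06 and -0.24 for endothelium. The cytokine list had a median of -0.15 and the hepatocyte list a mean of -0.47 under tests pointing up.

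**Figure D4:**
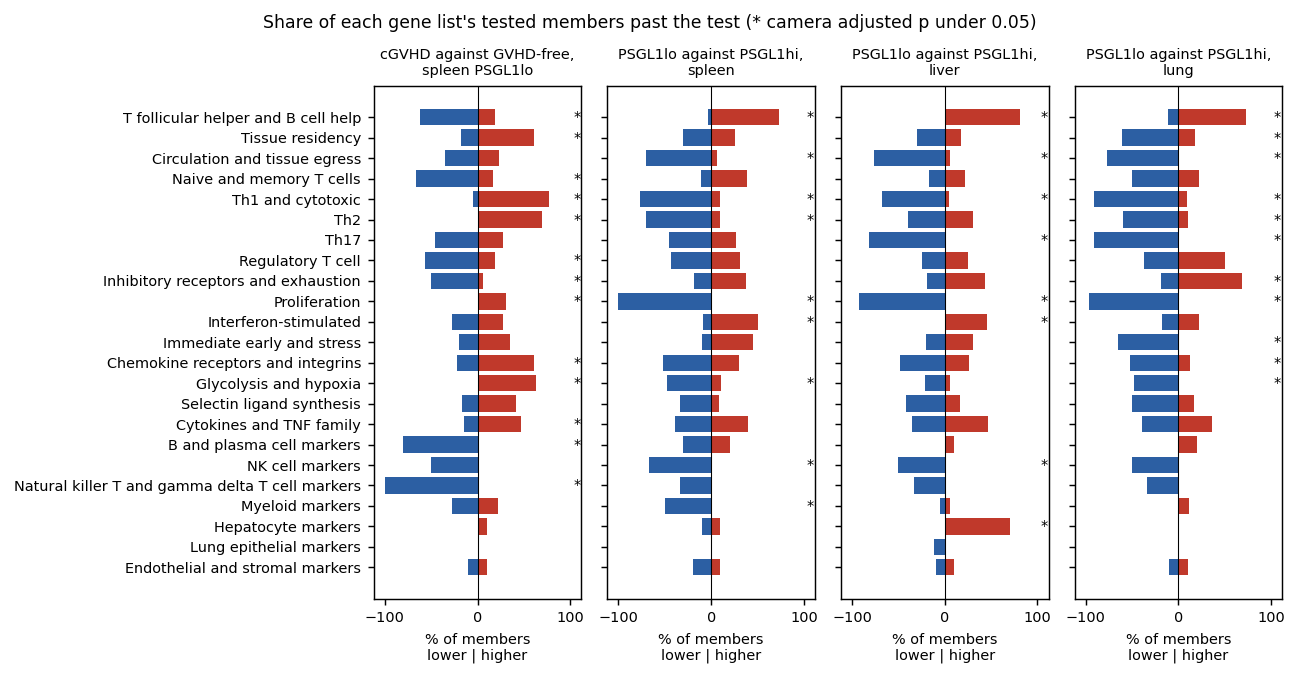
Percentage of tested members called higher (right) or lower (left) for 23 gene lists in the disease comparison and in PSGL1lo against PSGL1hi cells of spleen, liver and lung, with an asterisk where the list's adjusted p at the preset correlation was under 0.05. The follicular helper list has 16 of 26 members lower in the disease comparison and 19, 21 and 19 higher in spleen, liver and lung PSGL1lo cells.

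Across the 3 tissues, which share no libraries, 1380 genes were called in the same direction between PSGL1lo and PSGL1hi cells, and 211 in the test against a 1.5-fold change. Of the 1380 genes, 519 were higher and 861 lower, where independent lists of these lengths would share 24 and 57. Sostdc1 was higher in each PSGL1lo fraction, with log2 changes of 4.05, 4.73 and 6.30 in spleen, liver and lung. Others were Lrig1 (3.25, 2.75 and 1.94), Cxcr5 (1.90, 1.78 and 2.21), Nsg2 (2.38, 1.99 and 1.87), Bace2 (1.45, 2.21 and 2.87), Tcf7 (2.37, 1.38 and 0.96) and Slamf6 (1.06, 1.31 and 1.48). Lower in each were Ifitm1 (-3.52, -4.06 and -2.39), the chemokine receptor Ccr2 (-2.57, -1.79 and -2.36), Gzma (-2.10, -2.24 and -3.46) and Klrg1 (-2.09, -1.54 and -2.27). The cytokine Il10 (-1.78, -1.72 and -1.69), the checkpoint receptor Havcr2 (-1.72, -1.70 and -1.11) and S1pr1 (-0.82, -1.62 and -1.49) were also lower in each. Of the genes called in both spleen and liver, 1733 of 1777 went the same way, in spleen and lung 2013 of 2337, and in liver and lung 2025 of 2062. Across genes, the log2 changes of spleen and liver correlated with Pearson's r of 0.38, those of spleen and lung with 0.36 and those of liver and lung with 0.44. Spearman's rho was 0.45, 0.38 and 0.52 in the same order, and genes are not independent replicates.

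Several heat shock and immediate early genes stood far higher in lung than in liver PSGL1lo cells (same library series), and other immediate early genes lower. The inducible heat shock gene Hspa1a averaged 1134 ± 83 CPM in lung and 3.62 ± 0.11 CPM in liver PSGL1lo cells (adjusted p = 3.3e-22), and its near-identical copy Hspa1b 1543 ± 116 and 8.91 ± 1.6 CPM. The cochaperone Dnajb1 stood at 992 ± 89 against 138 ± 10 CPM and the immediate early gene Nr4a1 at 673 ± 28 against 109 ± 9.9 CPM. Egr2 and Fosb, chosen after their values were seen, stood lower in lung, at 49.4 ± 7.7 against 114 ± 8.3 CPM and 262 ± 52 against 477 ± 106 CPM. The immediate early and stress list was called at the preset correlation and not with an estimated one. It was set as a sign of sample quality, from which tissue cannot be told apart in either fraction. Ccr7 (2.20 ± 0.12), S1pr1 (1.64 ± 0.09), Klf2 (1.49 ± 0.13) and Bcl6 (1.33 ± 0.11) were higher in lung. Gzmb (-2.84 ± 0.16), Prdm1 (-0.96 ± 0.10) and Il21 (-0.62 ± 0.09) were lower.

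The comparison of lung with liver PSGL1lo cells gave 5504 changed genes, 2695 higher and 2809 lower in lung, and 1308 in the test against a 1.5-fold change. Smaller differences were Cd69 at 0.81 ± 0.09, Foxp3 at 0.68 ± 0.15, Icos at 0.61 ± 0.07, Cd40lg at 0.48 ± 0.08, Cxcr6 at -0.50 ± 0.08 and Selplg at -0.46 ± 0.09. Pdcd1 was higher by 0.29 ± 0.07 (adjusted p = 0.0032), a call lost without lung PSGL1lo replicate 1 (0.22). Ifng was higher by 0.25 ± 0.07 (adjusted p = 0.011), lost without liver PSGL1lo replicate 1 (0.20) or lung PSGL1lo replicate 2 (0.17). Cxcr5 (0.16 ± 0.09) and Itgae (0.11 ± 0.09) did not pass the test (adjusted p = 0.16 and 0.37). Of the leading decreases in lung, the gelatinase Mmp9 stood at 8.16 ± 0.75 against 116 ± 10 CPM and the T cell surface gene Cd7 at 26.6 ± 11 against 282 ± 28 CPM. Atp8a2 stood at 5.77 ± 1.6 against 54 ± 5.1 CPM, and Dtx1, a regulator of Notch signalling, at 22.4 ± 8.1 against 171 ± 6.8 CPM. Cd8a was lower too, at 2.73 ± 0.5 against 17.7 ± 1.3 CPM. The macrophage genes Lyz2 and Mmp12 averaged 799 ± 235 and 87.3 ± 23 CPM in lung and 13.9 ± 10 and 0.282 ± 0.2 CPM in liver PSGL1lo cells. Slc7a2 averaged 40.3 ± 9.9 and 0.0211 ± 0.03 CPM.

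Between these tissues no list call held with an estimated correlation. Immediate early and stress genes were higher in lung in 14 of 20 and lower in 4 members, the same adjusted over the list alone (list adjusted p = 7.37e-08, adjusted p = 0.0999 with an estimated correlation). Atf3 was higher by 4.91 ± 0.17, and the growth factor gene Areg averaged 38.2 ± 0.72 against 2.02 ± 0.47 CPM. Myeloid markers moved with them, 13 of 18 higher and 4 lower, also over the list alone (list adjusted p = 9.15e-08, adjusted p = 0.152 with an estimated correlation). All 26 proliferation genes were lower in lung, also adjusted over the list alone (list adjusted p = 3.12e-17, adjusted p = 0.123 with an estimated correlation), Rrm2 by -1.54 ± 0.11. Interferon-stimulated genes were lower in 19 of 22 members, the same count adjusted over the list alone (list adjusted p = 7.54e-09, adjusted p = 0.123 with an estimated correlation), Isg15 by -1.22 ± 0.14. Hepatocyte markers were lower in 9 of 10 and higher in 1, over all genes and over the list alone (list adjusted p = 2.63e-06, adjusted p = 0.0999 with an estimated correlation), with Alb at 0 CPM in lung PSGL1lo libraries. Lung epithelial markers were higher in 6 of 9 and lower in 1, likewise (list adjusted p = 0.0146, adjusted p = 0.168 with an estimated correlation). Scgb1a1 averaged 40.3 ± 54 CPM in lung PSGL1lo cells, a spread that exceeds the mean.

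T cell state lists also differed between lung and liver PSGL1lo cells, these 4 with the same counts adjusted over the list alone. Genes of Th1 and cytotoxic cells were lower in 12 of 22 and higher in 4 members (list adjusted p = 7.39e-05, adjusted p = 0.0999 with an estimated correlation). Naive and memory genes were higher in 11 of 18 and lower in 2 (list adjusted p = 7.39e-05, adjusted p = 0.123 with an estimated correlation). Follicular helper genes were higher in 16 of 26 and lower in 3 (list adjusted p = 5.68e-05, adjusted p = 0.0999 with an estimated correlation), and tissue residency genes higher in 14 of 23 and lower in 6 (list adjusted p = 0.00273, adjusted p = 0.125 with an estimated correlation).

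In PSGL1hi cells the same tissues differed in 5288 genes, 2764 higher and 2524 lower in lung, and 1165 in the test against a 1.5-fold change. Hspa1a was again far apart, at 1420 ± 109 CPM in lung and 3 ± 0.084 CPM in liver PSGL1hi cells (adjusted p = 1.8e-22). Ccr7 (3.40 ± 0.14), Bcl6 (2.17 ± 0.12) and Icos (1.66 ± 0.08) were higher in lung. Il21 (-2.11 ± 0.10), Mmp9 (-2.23 ± 0.12), Cd8a (-2.90 ± 0.11) and Gzmb (-1.25 ± 0.14) were lower. Immediate early and stress genes were higher in 17 of 20 and lower in 1, also adjusted over the list alone (list adjusted p = 5.68e-14, adjusted p = 0.0502 with an estimated correlation). Myeloid markers moved with them, 13 of 18 higher and 3 lower, also over the list alone (list adjusted p = 1.91e-06, adjusted p = 0.268 with an estimated correlation), Lyz2 at 630 ± 100 CPM in lung and 10.4 ± 5.3 CPM in liver PSGL1hi cells.

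Liver and lung PSGL1lo cells were each compared with spleen PSGL1lo cells, where the tissues also belong to different library series, so that tissue and library series cannot be told apart. Liver cells had less of the egress and lymph node homing genes S1pr1 (-1.45 ± 0.10) and Ccr7 (-1.73 ± 0.13) and of Il21 (-1.20 ± 0.09) than spleen cells. They had more Itgae (1.32 ± 0.11) and Cd40lg (0.90 ± 0.09). Adgrg1, an adhesion receptor gene of cytotoxic lymphocytes, averaged 78.5 ± 6.5 CPM in liver and 6.06 ± 0.17 CPM in spleen (adjusted p = 1.3e-15). Lung cells had more Bcl6 (1.98 ± 0.12), Cd40lg (1.37 ± 0.09) and Hspa1a (6.78 ± 0.11) than spleen cells, and less Il21 (-1.82 ± 0.09) and Gzmb (-2.23 ± 0.16). In liver 7952 genes differed from spleen, 3958 higher and 3994 lower, and in lung 8274, 4085 higher and 4189 lower. Of these, 3221 and 3539 passed the test against a 1.5-fold change. Among the furthest apart were RNAs without a poly(A) tail, such as the RNA of the mitochondrial RNA-processing enzyme, Rmrp. It averaged 10552 ± 1805 CPM in spleen, 0.536 ± 0.58 CPM in liver and 0.981 ± 0.13 CPM in lung PSGL1lo cells. Proliferation genes were lower than in spleen for 24 of 26 members in liver and higher for 1 (list adjusted p = 1.91e-06, adjusted p = 0.541 with an estimated correlation). In lung they were lower for 25 of 26 (list adjusted p = 7.4e-15, adjusted p = 0.348 with an estimated correlation). Th1 and cytotoxic genes were higher in liver for 17 of 22 (list adjusted p = 1.24e-06, adjusted p = 0.14 with an estimated correlation), and all of these counts were the same adjusted over the list alone. Beside them, the CD8 T cell genes Cd8a and Cd8b1 averaged 4.73 ± 0.58 and 7.34 ± 0.9 CPM in spleen and 17.7 ± 1.3 and 12 ± 1.2 CPM in liver PSGL1lo cells, and the NK gene Klre1 0.662 ± 0.012 and 5.02 ± 0.1 CPM.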

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

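The differences of the PSGL1lo effect between tissues were planned contrasts, while the tests of explanations for the spleen RNAs and for the Th1 and cytotoxic genes were chosen after these results were seen. Apart from those 2 patterns of the report, each gene or number of genes in this part stands here because the log2 ratio of PSGL1lo to PSGL1hi differed between tissues by edgeR's interaction test (adjusted p under 0.05). The gene lists in this part were tested with camera on the same differences. The lung and liver effects come from 1 library series. The spleen effect lies within the other series, so a difference of liver or lung from spleen is also one between series.

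Between lung and liver the effect differed in 823 genes, 287 higher and 536 lower in lung, of which 107 passed the test against a 1.5-fold difference. The count was 1337 without liver PSGL1lo replicate 2, 492 without liver PSGL1hi replicate 1, 481 without liver PSGL1hi replicate 2, 528 without lung PSGL1lo replicate 1 and 529 without lung PSGL1hi replicate 2. Il21 was higher in PSGL1lo cells of both tissues, by 0.34 in liver and 1.83 in lung, a difference of 1.49 ± 0.13 (adjusted p = 5.4e-07). Icos and Cd40lg, higher in PSGL1lo cells of liver (0.46 and 0.27), were lower in those of lung (-0.60 and -0.47), differing by -1.05 ± 0.10 and -0.74 ± 0.12. Bcl6 was higher in both tissues with a difference of -0.85 ± 0.16, and Ccr7 stood at 1.18 in liver and -0.02 in lung (-1.21 ± 0.19). Gzmb (-1.59 ± 0.20), Prdm1 (-0.88 ± 0.13) and Itgae (-0.86 ± 0.13) were lower in PSGL1lo cells of both tissues and further down in lung. Foxp3 differed by -0.68 ± 0.19 (adjusted p = 0.037). That call was lost without any 1 of liver PSGL1hi replicate 1 (-0.58), liver PSGL1lo replicate 2 (-0.57), lung PSGL1hi replicate 1 (-0.66) or 2 (-0.69) and lung PSGL1lo replicate 1 (-0.63) or 2 (-0.72), and with voom, only these groups or only the library series in the model (-0.65 in each). Cd69 differed by -0.60 ± 0.13, lost without lung PSGL1hi replicate 2 (-0.52) or lung PSGL1lo replicate 1 (-0.49). Selplg itself differed by -0.51 ± 0.12 (adjusted p = 0.014), lost without liver PSGL1hi replicate 1 (-0.49), lung PSGL1hi replicate 2 (-0.46) or lung PSGL1lo replicate 1 (-0.39).

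Of the genes named by size of this difference, the calcium pump gene Atp2b2 stood at 0.60 in liver and 3.55 in lung (2.95 ± 0.24), and the calcium channel gene Cacna1d at 1.25 and 3.39 (2.14 ± 0.24). Itgax, the CD11c integrin chain, averaged 1.94 ± 0.47 CPM in PSGL1lo and 23.4 ± 1.6 CPM in PSGL1hi cells of liver and 64.4 ± 27 and 84.8 ± 15 CPM in lung, a difference of 3.23 ± 0.32. Mmp9 differed by -1.60 ± 0.17, the receptor-modifying protein gene Ramp3 by -1.64 ± 0.21 and Cxcl10 by -1.74 ± 0.18 (2.52 in liver and 0.79 in lung). The tissue residency list shares members, Nr4a1 among them, with the immediate early and stress list, so their calls are not independent. The residency list was lower in lung relative to liver in 11 of 23 members and higher in 0, or 15 and 1 adjusted over the list alone (list adjusted p = 4.18e-08, and adjusted p = 0.0406 with an estimated correlation). Lower with it were the immediate early and stress list, 11 of 20 lower and 1 higher (15 and 2 adjusted over the list alone, list adjusted p = 2.96e-07), and the proliferation list, 16 of 26 lower (23 adjusted over the list alone, list adjusted p = 5.74e-20), each with adjusted p = 0.1 with an estimated correlation. Myeloid markers were called higher, with 1 of 18 members higher and 0 lower, or 2 and 0 adjusted over the list alone (list adjusted p = 0.0337, adjusted p = 0.587 with an estimated correlation). That call was lost without a filter (0.0502) and without liver PSGL1hi replicate 1 (0.576), lung PSGL1hi replicate 1 (0.28) or lung PSGL1lo replicate 2 (0.579) and turned without liver PSGL1lo replicate 2 (0.595). The inhibitory receptor list was higher in 7 of 16 and lower in 1, or 9 and 1 adjusted over the list alone (list adjusted p = 1.14e-06, adjusted p = 0.0315 with an estimated correlation).

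Between liver and spleen the effect differed in 943 genes, 364 higher and 579 lower in liver, 48 of them in the test against a 1.5-fold difference and 603 with only these groups in the model. Without 1 spleen library the count was 525 (PSGL1lo replicate 1), 357 (PSGL1lo replicate 2) and 466 (PSGL1hi replicate 2). Without 1 liver library it was 425 (PSGL1lo replicate 1), 2515 (PSGL1lo replicate 2), 458 (PSGL1hi replicate 1) and 343 (PSGL1hi replicate 2). Vcam1, an adhesion molecule of stromal cells and macrophages, was lower in PSGL1lo cells of spleen (-1.25) and higher in those of liver (1.34), with a difference of 2.59 ± 0.24 (adjusted p = 3e-06). The myeloid marker list was also called for this difference at the preset correlation, a call lost without liver PSGL1lo replicate 1. Itgae changed by -1.65 in spleen against -0.70 in liver (0.95 ± 0.14). The egress genes S1pr1 (-0.79 ± 0.13) and Klf2 (-1.01 ± 0.19) lay lower in liver, as did Atf3 (-2.51 ± 0.24) and Itgax (-2.79 ± 0.33). Il21 differed by -0.58 ± 0.12. The difference of Cd40lg, -0.46 ± 0.12 (adjusted p = 0.026), was lost without any 1 of liver PSGL1hi replicate 1 (-0.46) or 2 (-0.45), liver PSGL1lo replicate 1 (-0.44), spleen PSGL1hi replicate 1 (-0.42) or 2 (-0.49) and spleen PSGL1lo replicate 2 (-0.37).

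Between lung and spleen it differed in 2282 genes, 759 higher and 1523 lower in lung, and 329 passed the test against a 1.5-fold difference. Icos (-1.29 ± 0.10, adjusted p = 8.7e-08) and Cd40lg (-1.19 ± 0.12) were higher in PSGL1lo cells of spleen and lower in those of lung. Gzmb (-1.52 ± 0.21), Ccr7 (-1.14 ± 0.17), Prdm1 (-1.04 ± 0.14), Bcl6 (-0.85 ± 0.17) and S1pr1 (-0.67 ± 0.13) lay lower in lung. Klf2 differed by -0.78 ± 0.19, or -0.49 without lung PSGL1lo replicate 1. Il21 lay higher by 0.91 ± 0.13. Pdcd1 differed by 0.40 ± 0.10, lost without lung PSGL1hi replicate 2 (0.35), lung PSGL1lo replicate 1 (0.33) or spleen PSGL1lo replicate 2 (0.35). Cd69 differed by -0.40 ± 0.13 (adjusted p = 0.043), lost with the filter of 5 CPM (-0.35) and without any 1 of lung PSGL1hi replicate 2 (-0.32), lung PSGL1lo replicate 1 (-0.28), spleen PSGL1hi replicate 1 (-0.32) and spleen PSGL1lo replicate 1 (-0.43) or 2 (-0.37).

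Of the genes named by size, 3 of 6 in the liver and spleen difference and 6 of 6 in the lung and spleen difference were RNAs without a poly(A) tail. They stood at under 5 CPM in each liver and lung group, the histones at under 1 CPM, so their fitted differences rest on few counts outside the spleen, depend on the model's prior count and give no size. Among replication-dependent histones, H2bc13 differed between liver and spleen by 2.98 ± 0.79, a call lost with voom (2.97) and without liver PSGL1hi replicate 2 (2.17), liver PSGL1lo replicate 1 (1.82) or spleen PSGL1lo replicate 2 (2.79). H3c11 differed by 2.65 ± 0.50, lost with voom (2.52) and without liver PSGL1lo replicate 1 (1.84). Between lung and spleen H3c7 differed by 4.35 ± 0.53 and H4c2 by 3.28 ± 0.59. H4c6 differed by 4.08 ± 1.11, lost with voom (3.39) and without lung PSGL1hi replicate 1 (4.14) or 2 (4.01) or lung PSGL1lo replicate 2 (2.28). Of the small nucleolar RNAs, Snora81 differed by -1.74 ± 0.28 between liver and spleen and by -2.43 ± 0.28 between lung and spleen, and Snora64 by -2.03 ± 0.44. Snord47 differed by -3.10 ± 1.04 (adjusted p = 0.045). It was lost with the filter of 5 CPM (-3.05), voom (-3.10) and only these groups (-3.07), and without any 1 of lung PSGL1hi replicate 1 (-2.81) or 2 (-3.36), lung PSGL1lo replicate 1 (-4.35) or 2 (-2.47) and spleen PSGL1hi replicate 2 (-2.90).

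Small RNAs and replication-dependent histone RNAs stood higher in the spleen libraries than in those of liver and lung. Of these 235 RNAs, which lack a poly(A) tail, 77% were higher in all 6 spleen libraries, against 12.4% of 13543 other genes (Malat1 and Rn45s left out of both). Fewer dividing cells are argued against as the whole cause in liver. From spleen to liver PSGL1lo cells the histone median of -7.19 lay -6.56 from that of the proliferation list (-0.63), where the members' spread was 0.98. From spleen to lung the medians were -7.01 for histones and -1.86 for proliferation genes. Fewer dividing cells stay open as part of the cause, since proliferation genes were lower than in spleen in both tissues. The histones named above rest on few counts in liver and lung, so the size of such falls depends on the model's prior count. RNA selection that differed between the library series remains open, and may account for the pattern, as the histones moved by -7.55 more than the 7 histone variants that carry a tail (median 0.36). The labels give the same library protocol for all samples and state no such difference. The tissue itself remains open as well, since tissue and series cannot be told apart.

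Th1 and cytotoxic genes were lower in PSGL1lo than PSGL1hi cells of each tissue, together with Cd8a and Cd8b1, although the sort was of CD4+ cells. CD8 T cells of 1 profile in the PSGL1hi sorts of liver and lung are argued against as the whole cause. For each CPM of Cd8a and Cd8b1 lost, the 15 genes lower in both tissues lost a median of 5.32 times as much in lung as in liver (quartiles 3.17 and 11), while CD8 T cells that differ between tissues stay open. NK cells as the whole cause are argued against in liver, where Tyrobp and Fcer1g, abundant in NK cells, differed between fractions by only 1.63% of the Klrd1 difference. In spleen (31.8%) and lung (-18.4%) these genes cannot decide, because in PSGL1lo cells they already stood at 56.8% and 103% of that difference. Ncr1 and Klra8 of the NK list averaged only 0.065 and 0.022 CPM in spleen and 0.157 and 0.059 CPM in lung PSGL1hi cells. The Klrd1 differences there were 37 and 31.1 CPM. The NK list was nonetheless called lower in spleen and liver PSGL1lo cells. NK cells stay open in each tissue, in liver as part of the cause. So does a cytotoxic program of PSGL1hi CD4+ T cells, untested.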

How the results depend on the processing

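Across the alternatives, 7996 of 8337 values of the genes taken by the rule kept their call or stayed uncalled, 291 lost the call, 50 gained one and 0 reversed. Direction was compared only where the main fit or the alternative called the value. The rule took many of these genes for large called changes in these same data, which favours stable calls. Of the lost calls, 154 came from the test against a 1.5-fold change, which calls fewer genes by construction, and 104 from leaving out 1 library. Of 2806 values of gene lists, 2539 kept their call or stayed uncalled, 142 lost the call, 122 gained one and 3 reversed. These totals include leaving out RNAs without a poly(A) tail, which was chosen after seeing the data and gave 3778 changed genes for disease, 4393 in spleen, 2884 in liver and 4481 in lung. DESeq2's size factors shifted the median log2 change by -0.028 to 0.026. The test against a 1.5-fold change left 1181 genes for disease, 776 in spleen, 472 in liver and 1034 in lung, 48, 329 and 107 for the differences of liver from spleen, lung from spleen and lung from liver, 1308 and 1165 for lung against liver in PSGL1lo and PSGL1hi cells, 3221 and 3539 for liver and lung against spleen, and 211 changed alike in the 3 tissues. With only its own groups fitted, the liver and spleen difference gave 603 genes, where fewer samples estimate the spread. Leaving out 1 library moved the count to 1580 to 3689 in liver, 343 to 2515 for liver minus spleen and 481 to 1337 for lung minus liver, and the cause was not tested. The other counts stayed within 1.5 times, at 2641 to 2755 for disease, 3090 to 3947 in spleen, 3163 to 3555 in lung and 983 to 1353 changed alike. Of 253 list tests, 112 were called at the preset correlation, 19 with an estimated one and 170 by fry, which asks another question. The regulatory T cell list in lung reversed under fry (adjusted p = 0.00144, lower in PSGL1lo). When 1 library was left out, the myeloid list ranged from adjusted p = 0.000555 to 0.366 in liver and from 4.84e-08 to 0.595 for lung minus liver. It reversed in both without liver PSGL1lo replicate 2 (0.0366 and 0.595), and the cause was not tested. Replicate numbers are shared by the groups, but same-numbered libraries hardly deviated together (correlations of -0.08 to 0.10, highest between the fractions of liver, 0.08, and of lung, 0.10), so the design was not taken as paired. Counting noise in genes of low count pulls such correlations toward 0, so pairing is not excluded. The liver and lung libraries also carry a letter that follows the replicate number, with no meaning given in the labels. With the number as a block the counts were 3965 for disease, 4690 in spleen, 3130 in liver, 4788 in lung, 1299, 2573 and 988 for the tissue differences and 1488 changed alike, and 120 lists were called. The 8 gained with the block were the chemokine receptor (adjusted p = 0.0473) and immediate early lists (0.0131) in spleen, the myeloid list in lung (0.0486), the interferon-stimulated (0.0437), proliferation (0.0465) and Th1 and cytotoxic lists (0.0456) for lung minus spleen, and the circulation and Th2 lists (0.0359 in both) for liver against spleen. At the depth of these libraries a gene at 0 counts can stand at up to 0.0895 to 0.227 CPM, so differences under that were not detectable.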

Other observations

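The tests of the explanations in this part were chosen after the result was seen, and the genes named in it were chosen after their values were seen. A few genes that macrophages can express stood at or near 0 in GVHD-free spleen libraries and higher in cGVHD ones, although the myeloid list was not called (adjusted p = 0.448) and Adgre1 (45.3 against 30.5 CPM) and Itgam (14.4 against 6.42 CPM) stood higher in GVHD-free cells. The arginase gene Arg1 averaged 0 CPM in GVHD-free cells, 20.4 ± 2.1 CPM in cGVHD PSGL1lo and 42.6 ± 3.6 CPM in cGVHD PSGL1hi cells (n = 2 each), and Retnla 0, 9.2 ± 0.58 and 22.3 ± 3.5 CPM. The chemokine gene Ccl8 stood at 0.0609 ± 0.086, 16.9 ± 0.13 and 42.1 ± 6.7 CPM. Chil3, a chitinase-like protein of alveolar macrophages, reached 484 ± 120 CPM in lung PSGL1lo and 436 ± 100 CPM in lung PSGL1hi libraries, against 7.09 ± 5.3 and 4.19 ± 3.4 CPM in those of liver.

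Some genes known from plasmacytoid dendritic cells and basophils, for which no list was tested, stood higher in spleen PSGL1hi than PSGL1lo libraries. Siglech, a surface lectin of plasmacytoid dendritic cells, averaged 23.3 ± 0.98 CPM there and 3.05 ± 0.16 CPM in GVHD-free spleen PSGL1lo cells. In cGVHD spleen PSGL1lo cells it stood at 0.107 ± 0.059 CPM, at or below the level of 3 counts. The transcription factor Spib (7.35 ± 0.063 against 0.55 ± 0.15 CPM), Jchain (44.9 ± 5.9 against 4.22 ± 1.4 CPM), also in the B and plasma cell list that was not called there (adjusted p = 0.343), and Ly6d (4.27 ± 0.62 against 0.0327 ± 0.046 CPM) showed the same order between cGVHD spleen PSGL1hi and PSGL1lo cells. The basophil protease genes Mcpt8 and Prss34 averaged 2.69 ± 0.1 and 4.49 ± 0.26 CPM in spleen PSGL1hi cells and 0.0327 ± 0.046 and 0.289 ± 0.22 CPM in spleen PSGL1lo cells. The titin gene Ttn, a muscle transcript among the leading genes of spleen PSGL1lo cells, also separated the fractions in liver (26.5 ± 6.7 against 7.4 ± 2.4 CPM) and lung (50.7 ± 11 against 12.9 ± 2.2 CPM). The deepest library, liver PSGL1lo replicate 1 with 33532595 counts, had the fewest genes detected, 14036, where the highest number was 15445, and its sample index number lies apart from the run of those of the other liver and lung libraries.

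At 2 CPM or more in GVHD-free cells, 39 genes stood at least 10 times above every cGVHD group, among them Zan, Gpr83 (27.3 ± 0.61 CPM), Kcnf1 (19.4 ± 2.4 CPM), Ifi202b (16.8 ± 2 CPM) and the class I genes H2-Q2 (85 ± 1.2 CPM) and H2-Q1 (7.54 ± 1.7 CPM). Cells of the recipient strain in the GVHD-free libraries may be a source, although the sort was of donor-derived cells. Of the 38 pattern genes with a place in the reference annotation, 5 lay in the histocompatibility block, in which donor and recipient strains differ, against 125 of 13680 tested genes (odds ratio 17.1, Fisher's exact p = 2.32e-05). The test was prompted by the pattern itself. It also counts the H2-Q genes, whose reads can match several copies, as independent, so its p-value overstates the support. B cells cannot be told apart from other sources, since Cd79a and Cd79b stood -6.26 CPM from the sum of Pax5 and Ms4a1, which belong to the pattern themselves and so decide nothing, while 8 of 10 B and plasma cell markers were lower in cGVHD (list adjusted p = 9.13e-05, adjusted p = 0.0237 with an estimated correlation). T cells newly formed from the donor marrow, the only donor graft of GVHD-free animals, stay open as a biological explanation, untested. That limit holds for the disease comparison as a whole.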
